A study of Mus musculus with 9 samples.

How the data were processed

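Whole retinas of mice at postnatal day 8 had been profiled on an Affymetrix whole-transcript mouse array in 3 groups: wild type (WT), Rb knockout (Rb KO) and Rb/p107 double knockout (Rb/p107 DKO, DKO below). There were 3 arrays per group, 9 in all, on a mixed background of inbred strains. The series design calls the arrays of a group biological replicates, and more arrays than 3 per group would be needed for a narrower precision. Per the labels, RNA was isolated with a column kit, RNA with an integrity number above 8 was used, and cDNA was amplified, labelled with biotin and hybridized with the maker's whole-transcript kits. The deposited values are log2 intensities, summarised per probe set by robust multi-array averaging (RMA) per the submitters' processing notes. The software version and the genome build of the array annotation were not given in the sources used here.

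The deposited table held 59649 probe sets, of which 52917 were transcript clusters and 6732 were controls (5222 negative, 1324 positive, 155 spike-in and 23 background probe sets, among others). Gene symbols came from the deposited platform annotation. Of the transcript clusters 24646 had 1 gene symbol, 1795 had several and 26476 had none listed. A gene was represented by its probe set with the highest mean over all 9 arrays, which gave 24259 genes, with no filter on dim probe sets. Symbols were matched to a reference gene table of assembly GRCm38.p6, used only for names and for which genes neighbour one another. It held 24007 of the genes, and 658 symbols were updated through it. The table had next to no transcript clusters on chromosomes 1, 2 and 3, where 5, 5 and 3 protein-coding genes were tested, so that Rbl1 and the other genes of these chromosomes were not analysed here. On the other autosomes between 76.7% and 92.2% of protein-coding genes were tested, on the X chromosome 78.6%. In the 9 arrays between 27.2% and 36.4% of the genes lay above the 95th percentile of the negative control probe sets of the same array, which was 7.94 to 8.5. A gene was taken as not above background in a group when none of its 3 arrays lay above it, a check chosen after the data were seen. Background readings below are readings not above that percentile. They can still lie above the median of the negative controls, which was 5.52 to 5.83 in the 9 arrays. Where the lower group was not above background, the bound written with "at least" is the mean of the higher group minus the mean, over the arrays of the lower group, of the larger of that percentile and the reading of the gene. It is an estimate from group means that leaves out the spread between arrays, so it is no confidence limit.

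Groups were compared by linear models in limma 3.58.1 under R 4.3.3, fitted to the group means of all 9 arrays with 6 residual and 4.69 prior degrees of freedom. Variances were moderated without trend and without robust estimation. Adjusted p is the Benjamini-Hochberg value over all genes of a comparison, and genes were called at an adjusted p under 0.05. SE is the standard error of a log2 fold change. A moderated F test over both contrasts against WT asked for any difference among the 3 groups. Gene lists were tested with the camera method of limma at a fixed correlation of 0.01 between genes, adjusted over the lists of a comparison and called under 0.05. A list needed 4 measured members. Counts of members that rose and fell are given at the adjusted p over all genes and, separately, adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

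The 34 gene lists held 939 genes, of which 675 were measured, and 33 lists could be tested. They covered G1/S and DNA replication, G2/M and mitosis, DNA repair and checkpoints, pocket proteins with CDK inhibitors and G1 cyclins, p53 targets, apoptosis, rods, cones, photoreceptor precursors and fate, bipolar, amacrine, starburst amacrine, horizontal and ganglion cells and Muller glia. Others covered gliosis and stress, microglia and macrophages, complement and antigen presentation, interferon-stimulated genes, progenitors, synapses, mitochondrial electron transport, glycolysis and lactate, hypoxia, Polycomb and DNA methylation, lens, pigment epithelium, endothelium, pericytes with smooth muscle and fibroblasts, astrocytes and oligodendrocytes, erythrocytes, immediate early genes, clock output and sex-linked genes. The erythrocyte list had 3 measured members and was not tested.

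The groups, tests, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule named Rb1, Rbl1 and Rbl2, the 10 largest rises and 10 largest falls of each comparison against WT (5 and 5 between the mutants) among called genes whose arrays did not overlap between the groups, leaving out predicted, microRNA, small nucleolar RNA and olfactory receptor symbols, and from each called list up to 2 rising and 2 falling members with the lowest p, or, where none passed, up to 2 with the lowest p as values only. Xist and the genes named in the closing section outside this rule were chosen after their values were seen. Shared calls were set beside the overlap of independent lists and beside 100 simulations of unchanged groups that shared 3 controls. Genes called on each chromosome were tested with Fisher's exact test, neighbouring calls with 10000 permutations of the positions, and differences of list medians with 10000 bootstrap draws over genes.

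The procedure was tested on simulated data with the means and variances of the 24259 genes, drawn independently between genes, with 200 changed genes in each of 10 draws per comparison. Of genes changed by 0.5, 1 and 2 on the log2 scale, 67.8%, 99.1% and 100% were called in Rb KO against WT, 70.7%, 99.6% and 100% in DKO against WT, and 67%, 98.4% and 99.8% in DKO against Rb KO. Wrong calls made up 5.53%, 5.11% and 4.85% of calls. A list of 30 genes shifted by 0.5 was called in 10 of 10 draws in each comparison, at the fixed and at an estimated correlation, and unshifted lists were called 2, 2 and 2 times in total. In unchanged data 2, 1 and 1 lists and 0, 2 and 6 genes were called over all draws.

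The alternatives were a replicate block, only the 6 arrays of the groups compared, a variance trend, a robust prior, no variance shrinkage, array weights, renewed quantile normalization, median centring, only the genes brighter than the median gene, all probe sets, the mean of the probe sets of a gene, an adjusted p under 0.01, a minimum of 1.5-fold, a sex covariate and leaving out each array. List tests were repeated with an estimated correlation, with rotation tests (fry) and with ranks. Chosen after seeing the data were the separation of positive from negative control probe sets as a covariate, leaving out uncharacterised and multi-copy symbols, and leaving out WT replicate 2 and DKO replicate 2 together.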

Results

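Rb1, the targeted gene, showed only a small difference at its brightest probe set. Its log2 intensities were 10, 10.19 and 10.46 in the WT arrays, 9.85, 10.02 and 9.86 in the Rb KO arrays, and 9.74, 10 and 9.85 in the Rb/p107 DKO arrays (DKO below). The log2 fold change was -0.31 (SE 0.117, 3 arrays per group, adjusted p = 0.0793) in Rb KO against WT and -0.36 (SE 0.117, adjusted p = 0.0423) in DKO against WT. The former passed without WT replicate 1 (adjusted p = 0.0302), and the latter call ended without WT replicate 2 or 3, any Rb KO replicate, or DKO replicate 1 or 3 (adjusted p = 0.0521 to 0.153). The other Rb1 probe sets were not above the 95th percentile of the negative control probe sets (7.94 to 8.5) in any of the 9 arrays. The dimmest read 3.46 to 4.35 in WT and 5.61 to 6.33 in the mutants. In the fit to all probe sets it was called higher in Rb KO (2.01, adjusted p = 3.5e-04) and DKO (2.23, adjusted p = 1.28e-04). As these are background readings, they give no measured fold change. The middle probe set did not pass (adjusted p = 0.226 and 0.165). With the mean of the 3 probe sets the direction turned, to 0.68 in Rb KO (adjusted p = 0.00963) and 0.74 in DKO (adjusted p = 0.00468), a turn that rests on these background readings. Which part of the transcript each probe set reads was not determined here, and a whole retina may hold cells that kept the gene. The knockout could therefore not be judged from these values, nor the share of cells that carried it. Rbl1, which encodes p107, was not analysed here. Rbl2, which encodes the related protein p130, did not pass in either mutant, with log2 fold changes of -0.17 (SE 0.076, adjusted p = 0.126) and -0.22 (SE 0.076, adjusted p = 0.055).

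**Figure D1:**
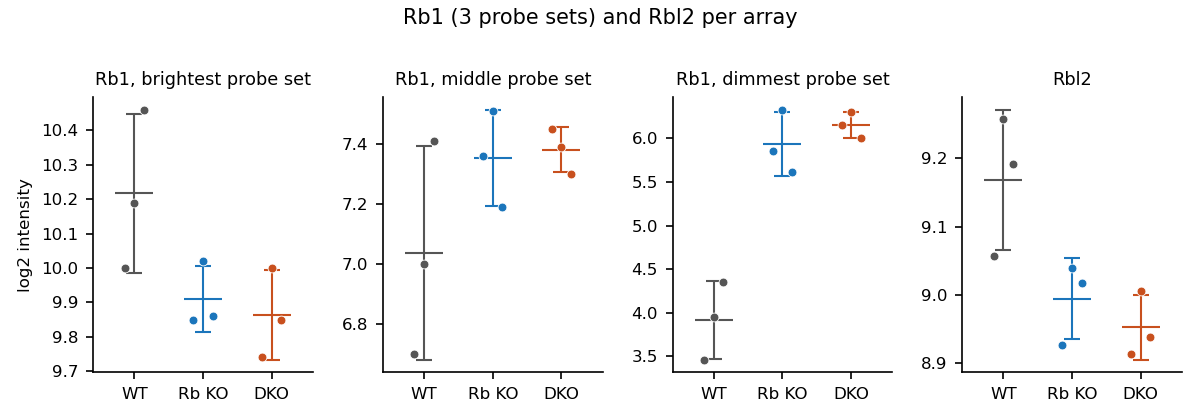
Log2 intensity (vertical axis) of the 3 Rb1 probe sets and of Rbl2 in each array of WT, Rb KO and DKO (horizontal axis); points are arrays, horizontal lines group means and bars standard deviations over 3 arrays. The brightest Rb1 probe set had slightly lower means in both mutants, and the others were not above the 95th percentile of the negative control probe sets in any array.

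WT was well separated from both mutants. The first principal component held 66.4% of the variance and set WT apart. Correlations between arrays of the same group were 0.992 to 0.998, against 0.976 to 0.985 between WT and Rb KO and 0.972 to 0.98 between WT and DKO. Between Rb KO and DKO they were 0.992 to 0.995, below those within Rb KO (0.996 to 0.997) and within DKO (0.997 to 0.998). Of 24259 genes, 5923 (24.4%) differed in Rb KO against WT, 7113 (29.3%) in DKO against WT and 617 (2.54%) in DKO against Rb KO, and 6962 differed among the 3 groups. In 2117, 2672 and 240 of these calls no array of either group lay above the 95th percentile of its negative control probe sets, so that the calls rest on background readings and their sizes were not measured. In a further 918, 1110 and 98 no array of the lower group did. For those the fitted difference is no measured size, and a lower bound was taken against that percentile. Between WT and each mutant the separation of positive from negative control probe sets also differed somewhat (area under the curve 0.944, 0.954 and 0.932 in WT, 0.928, 0.935 and 0.935 in Rb KO, and 0.929, 0.927 and 0.936 in DKO). DKO replicate 2 stood apart in sex-linked and lens genes: its Xist intensity was 5.47, against 11.44 to 12.15 in the other arrays, and its Y-linked genes averaged 8.62, against 4.73 to 4.92.

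In Rb KO retinas at postnatal day 8, genes of the cell cycle rose and genes of photoreceptors fell. Mki67, a marker of cycling cells, rose by 5.04 on the log2 scale (SE 0.130, 3 arrays per group, adjusted p = 1.6e-08), and Top2a, the topoisomerase of mitotic chromosomes, by 4.67 (SE 0.129). Set against the percentile of the negative controls, these were rises of at least 17.5-fold and at least 6.52-fold. Opn1mw, the medium-wavelength cone opsin, fell by 3.73 (SE 0.347, adjusted p = 3.4e-05, at least 5.73-fold lower), and Slc24a1, the rod ion exchanger, by 3.21 (SE 0.371). In all 2465 genes rose and 3458 fell (3033 and 3238 with renewed quantile normalization), 433 and 324 of them at least 2-fold, with a median log2 fold change of -0.05 over all genes.

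The other large rises in Rb KO were Pbk (4.32, SE 0.122), Esco2 (4.26, SE 0.142), Hmmr (4.18, SE 0.141), Rrm2 (4.18, SE 0.127), E2f8 (3.97, SE 0.115), Ulbp1 (3.94, SE 0.154), Atad2 (3.74, SE 0.123) and Kif15 (3.63, SE 0.133). No WT reading of these 8 genes lay above the percentile of the negative controls, so their order was not measured, and the bounds ran from at least 0.75 for Kif15 to at least 2.36 for Rrm2. Of these, Ulbp1 encodes a ligand of a natural killer cell receptor and the others serve S phase, chromosome cohesion or mitosis. The other large falls were Lrtm1 (-3.06, SE 0.441), Cds1 (-2.61, SE 0.239), Guca1b (-2.52, SE 0.229), Cabp4 (-2.47, SE 0.267), Pde6c (-2.44, SE 0.402), Pde6a (-2.39, SE 0.350), Drd4 (-2.37, SE 0.237) and Il33 (-2.32, SE 0.337). Lrtm1, Cds1, Guca1b, Drd4 and Il33 were not above that percentile in any Rb KO array, with falls of at least 2.23, 1.27, 1.65, 2.25 and 1.01. Guca1b, Cabp4, Pde6c, Pde6a and the dopamine receptor gene Drd4 are expressed in photoreceptors.

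Of 41 measured genes of G1/S and DNA replication, mostly targets of the E2F factors that Rb restrains, 40 rose and 1 fell in Rb KO (40 and 1 adjusted over the list alone), with a median log2 fold change of 1.98 and a list-test adjusted p of 5.6e-52. The fall was E2f3 (-0.30, SE 0.091, adjusted p = 0.0323), a call that ended without WT replicate 1 or 2, Rb KO replicate 2 or 3, or DKO replicate 1 or 3 (adjusted p = 0.0504 to 0.102). All 36 genes of G2/M and mitosis rose (36 adjusted over the list alone), with a median of 2.75 and a list test at adjusted p = 4.7e-55. DNA repair and checkpoint genes rose in 25 of 26 cases (26 adjusted over the list alone), with a median of 1.45 and a list test at adjusted p = 7.7e-34, among them Brip1 and Chek1, which were not above the percentile of the negative controls in any WT array and rose by at least 0.55 and 0.61. Each of these 3 list calls was lost when the correlation between genes was estimated from the 9 arrays (adjusted p = 0.15 with an estimated correlation in each).

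Among 18 pocket protein, CDK inhibitor and G1 cyclin genes, 9 rose, 1 fell and 8 did not pass in Rb KO (9 and 2 adjusted over the list alone), with a median of 0.39 and a list test at adjusted p = 2.4e-06 (adjusted p = 0.15 with an estimated correlation). Both a kinase and inhibitors of the cell cycle rose: Cdk2 by 2.51 (SE 0.093) and Cdkn1a, which encodes p21, by 2.69 (SE 0.108, 6.47-fold). Ccnd3 was the fall (-0.28, SE 0.091, adjusted p = 0.0441), a call that ended without WT replicate 1 or 2, Rb KO replicate 2 or 3, or any DKO replicate (adjusted p = 0.0637 to 0.164). Retinal progenitor genes rose in 12 of 16 cases and 1 fell (14 and 1 adjusted over the list alone). Their median was 0.71, and the list test gave adjusted p = 3.3e-10 (adjusted p = 0.15 with an estimated correlation). Hmgb2 stood at 2.54 (SE 0.127), Fabp7 at 1.63 (SE 0.119) and Gadd45a at -0.52 (SE 0.098). Polycomb and DNA methylation genes rose in 8 of 18 cases and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.22 and a list test at adjusted p = 1.7e-05 (adjusted p = 0.15 with an estimated correlation). The replication-linked Hells (3.21, SE 0.126) and Uhrf1 (2.30, SE 0.114) were among these rises, and both are also members of the DNA replication list. Ezh1 (-0.48, SE 0.106) and Dnmt3a (-0.34, SE 0.080) were the falls.

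**Figure D2:**
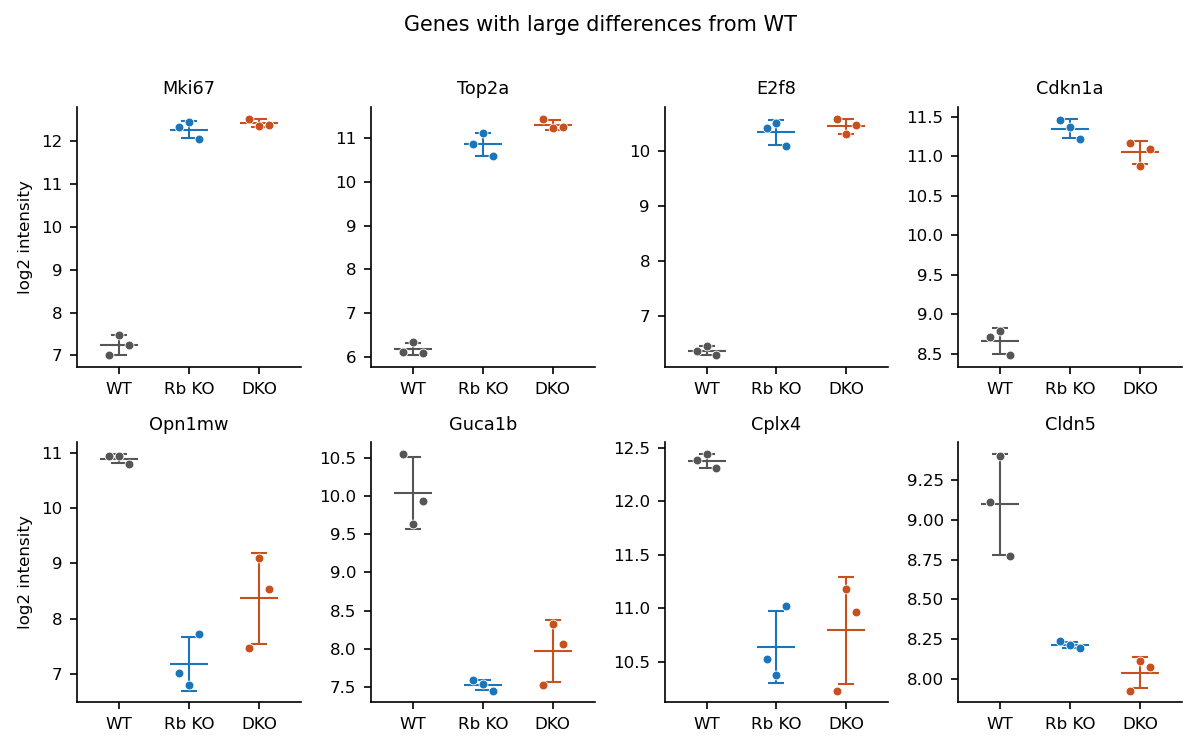
Log2 intensity (vertical axis) of 8 genes in each array of WT, Rb KO and DKO (horizontal axis); points are arrays, horizontal lines group means and bars standard deviations over 3 arrays. Mki67, Top2a, E2f8 and Cdkn1a lay above WT in every mutant array, and Opn1mw, Guca1b, Cplx4 and Cldn5 below.

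Photoreceptor genes were lower in Rb KO across both rods and cones. Of 37 rod genes 35 fell and none rose (35 adjusted over the list alone). The list had a median of -1.25 and an adjusted p of 1.4e-17 (adjusted p = 0.30 with an estimated correlation). Susd3 stood at -1.79 (SE 0.159) and Guca1b at -2.52. Of 11 cone genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -1.11 and a list test at adjusted p = 5.7e-04 (adjusted p = 0.30 with an estimated correlation). Pde6h (-2.08, SE 0.141) and Opn1mw fell, and Otop3 rose (0.47, SE 0.125, adjusted p = 0.0192), a call that ended without WT replicate 3, Rb KO replicate 1 or Rb KO replicate 3 (adjusted p = 0.0511 to 0.0688). Photoreceptor precursor and fate genes moved both ways, 5 up and 4 down of 11 (5 and 4 adjusted over the list alone), with a median of 0.18 and no list call (adjusted p = 0.10).

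Bipolar cell genes fell in 20 of 28 cases in Rb KO and 2 rose (21 and 3 adjusted over the list alone). At a median of -0.89 the list test gave adjusted p = 1.4e-05 (adjusted p = 0.40 with an estimated correlation). Car8 fell by 2.12 (SE 0.262) and Sebox by 1.22 (SE 0.104), while the transcription factor genes Nfib (1.29, SE 0.123) and Prdm8 (0.56, SE 0.079) rose. Starburst amacrine genes fell in 5 of 10 cases and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.39 and a list test at adjusted p = 0.020 (adjusted p = 0.30 with an estimated correlation). The cholinergic genes Chat (-0.85, SE 0.096) and Slc5a7 (-1.42, SE 0.176) fell and Sema6a rose (0.30, SE 0.077), the last a call that ended without WT replicate 1 or Rb KO replicate 2 (adjusted p = 0.0542 and 0.0687). The starburst list call ended without WT replicate 2 (adjusted p = 0.089). Synaptic vesicle and presynaptic genes fell in 22 of 30 cases and none rose (22 adjusted over the list alone). The median was -0.51 and the adjusted p of the list test 8.2e-08 (adjusted p = 0.30 with an estimated correlation). Examples were Cplx4 (-1.74, SE 0.222) and Rims2 (-0.83, SE 0.088).

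Genes of energy metabolism were also lower in Rb KO. Mitochondrial electron transport genes fell in 19 of 47 cases and 1 rose (24 and 1 adjusted over the list alone), with a median of -0.23 and a list test at adjusted p = 1.3e-04 (adjusted p = 0.50 with an estimated correlation). Ndufa4 stood at -0.58 (SE 0.093), Ppargc1b at -0.81 (SE 0.155) and Nrf1 at 0.28 (SE 0.074), the last a call that ended without WT replicate 1 or 3 or Rb KO replicate 1 (adjusted p = 0.0532 to 0.0541). That list call ended with the control separation of each array as a covariate (adjusted p = 0.069). Glycolysis and lactate genes fell in 11 of 19 cases and none rose (13 adjusted over the list alone). Their median was -0.34, and the list test gave adjusted p = 7.9e-05 (adjusted p = 0.30 with an estimated correlation). Hk1 stood at -0.89 (SE 0.106) and Eno2 at -0.98 (SE 0.123). Clock output genes fell in 10 of 15 cases (10 adjusted over the list alone), with a median of -0.35 and a list test at adjusted p = 1.1e-04 (adjusted p = 0.20 with an estimated correlation). Bhlhe41 stood at -1.15 (SE 0.113) and Dbp at -0.84 (SE 0.105).

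Microglia and macrophage genes rose in 12 of 30 cases in Rb KO and none fell (13 adjusted over the list alone). The list had a median of 0.33 and an adjusted p of 1.8e-05 (adjusted p = 0.40 with an estimated correlation). Cd68, the lysosomal marker of phagocytes, rose by 1.32 (SE 0.20) and the complement gene C1qb by 1.43 (SE 0.218). Interferon-stimulated genes went the other way, with 7 of 25 falling and none rising (8 adjusted over the list alone), with a median of -0.21 and a list test at adjusted p = 0.022 (adjusted p = 0.54 with an estimated correlation). Examples were Isg15 (-0.48, SE 0.084) and Irf7 (-0.43, SE 0.082). The interferon call ended without WT replicate 2 (adjusted p = 0.082) and without WT replicate 3 (adjusted p = 0.079). Immediate early genes rose in 9 of 24 cases and 4 fell (9 and 4 adjusted over the list alone). At a median of 0.12 the list test gave adjusted p = 0.0039 (adjusted p = 0.41 with an estimated correlation). Dusp1 stood at 1.48 (SE 0.119), Jun at 0.81 (SE 0.084), Nr4a1 at -0.59 (SE 0.111) and Ier3 at -0.53 (SE 0.109).

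Vessel and pigment epithelium genes were lower in Rb KO. Endothelial genes fell in 14 of 19 cases and none rose (15 adjusted over the list alone), with a median of -0.48 and a list test at adjusted p = 1.4e-05 (adjusted p = 0.30 with an estimated correlation). The barrier genes Slco1a4 stood at -1.86 (SE 0.267) and Cldn5 at -0.88 (SE 0.132). Pericyte, smooth muscle and fibroblast genes fell in 7 of 15 cases (9 adjusted over the list alone). The median was -0.22 and the adjusted p of the list test 8.3e-04 (adjusted p = 0.30 with an estimated correlation). Vtn stood at -2.32 (SE 0.243) and Dcn at -0.65 (SE 0.097). Pigment epithelium and melanocyte genes, which can enter a retina sample with attached tissue, fell in 13 of 18 cases and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.56 and a list test at adjusted p = 1.5e-06 (adjusted p = 0.15 with an estimated correlation). Pmel (-1.56, SE 0.135) and Ttr (-1.94, SE 0.172) fell and Ezr rose (0.49, SE 0.131, adjusted p = 0.020), a call that ended without WT replicate 1 or 3 or Rb KO replicate 1 or 2 (adjusted p = 0.0686 to 0.0842).

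Of the list members named in this comparison, Ccnd3, Chat, Dcn, Irf7, Isg15 and Slco1a4 were not above the percentile of the negative controls in any WT or Rb KO array, so the sizes given for them are differences between background readings. Cdk2, Uhrf1, Hells and Cd68 were not above it in any WT array, nor Susd3, Pde6h, Sebox, Slc5a7, Ppargc1b, Bhlhe41, Nr4a1, Cldn5, Vtn, Pmel and Ttr in any Rb KO array, and their sizes are not measured either. The remaining lists were not called in Rb KO against WT. Genes rose and fell as follows: 6 and 4 of 21 p53 targets, 5 and 3 of 18 apoptosis genes, 8 and 9 of 25 amacrine genes, 1 and 3 of 9 horizontal cell genes, 6 and 15 of 34 ganglion cell genes, 5 and 7 of 23 Muller glia genes, and 3 and 2 of 18 gliosis genes. Complement and antigen presentation genes gave 0 and 1 of 15, hypoxia genes 2 and 4 of 18, astrocyte and oligodendrocyte genes 0 and 6 of 14, and no gene passed among 13 lens, 5 sex-linked and 3 erythrocyte genes. Adjusted over the list alone the counts were 7 and 4 for p53 targets, 5 and 3 for apoptosis, 8 and 9 for amacrine, 1 and 4 for horizontal, 7 and 18 for ganglion, 6 and 9 for Muller glia and 4 and 4 for gliosis genes. For the others they were 0 and 1 for complement, 3 and 4 for hypoxia and 0 and 6 for astrocyte genes. The p53 targets had a median of -0.04 but a mean of 0.31 and an upward test (adjusted p = 0.063), and apoptosis genes a median of -0.03 but a mean of 0.14 and an upward test (adjusted p = 0.18). Amacrine genes (median -0.03, mean -0.07) had an upward test at adjusted p = 1, and Muller glia genes a median of 0.03 with a mean of -0.17.

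DKO retinas showed the same broad changes from WT as Rb KO retinas. Mki67 rose by 5.18 (SE 0.130, 3 arrays per group, at least 19.3-fold, adjusted p = 5.2e-09) and Top2a by 5.12 (SE 0.129, at least 8.9-fold). Opn1mw fell by 2.54 (SE 0.347, adjusted p = 3.2e-04) and Nrl, the rod-determining factor, by 1.53 (SE 0.130, adjusted p = 1.3e-05). In all 2960 genes rose and 4153 fell (3428 and 3984 with renewed quantile normalization), 551 and 404 of them at least 2-fold, with a median log2 fold change of -0.06 over all genes.

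Other large rises in DKO were Pbk (4.80, SE 0.122), Hmmr (4.50, SE 0.141), Esco2 (4.40, SE 0.142), Rrm2 (4.19, SE 0.127), E2f8 (4.08, SE 0.115), and the kinesin genes Kif23 (4.04, SE 0.133), Kif11 (3.99, SE 0.122) and Kif15 (3.96, SE 0.133). No WT reading of these 8 genes lay above the percentile of the negative controls, so their order was not measured, and the bounds ran from at least 1.06 for Esco2 to at least 2.94 for Kif11. Other large falls in DKO were Lrtm1 (-2.37, SE 0.441), Slc24a1 (-2.31, SE 0.371), Gucy2f (-2.20, SE 0.293), Ttr (-2.19, SE 0.172), Folh1 (-2.14, SE 0.237), Pde6c (-2.11, SE 0.402), Gpr152 (-2.09, SE 0.196), Rcvrn (-2.07, SE 0.320) and Guca1b (-2.07, SE 0.229). Folh1 was not above that percentile in any WT or DKO array, and Gucy2f, Ttr, Gpr152 and Guca1b in no DKO array, with falls of at least 1.63, 1.06, 0.33 and 1.66. Gucy2f, Pde6c, Rcvrn and Guca1b encode parts of phototransduction or its recovery.

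Of the 41 G1/S and DNA replication genes 40 rose and 1 fell in DKO (40 and 1 adjusted over the list alone), with a median of 2.0 and a list test at adjusted p = 3.9e-48, the fall again E2f3 (-0.37, SE 0.091). All 36 G2/M and mitosis genes rose (36 adjusted over the list alone), with a median of 3.05 and a list test at adjusted p = 2.1e-52, as did all 26 DNA repair and checkpoint genes (26 adjusted over the list alone), with a median of 1.82 and a list test at adjusted p = 6.2e-33, among them Chek1 and Brip1 with rises of at least 1.05 and 0.88. These 3 calls were lost too (adjusted p = 0.17 with an estimated correlation in each). Pocket protein, CDK inhibitor and G1 cyclin genes rose in 10 of 18 cases and 3 fell (11 and 4 adjusted over the list alone). Their median was 0.53, and the list test gave adjusted p = 1.9e-05 (adjusted p = 0.22 with an estimated correlation). Cdk2 (2.71, SE 0.093) and the inhibitor gene Cdkn2c (3.13, SE 0.141) rose, and Cdk6 (-0.54, SE 0.094) and Ccnd3 (-0.32, SE 0.091) fell, the last a call that ended without WT replicate 1 or 2 or DKO replicate 1 or 2 (adjusted p = 0.053 to 0.0846).

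Among 21 p53 targets, 7 rose and 2 fell in DKO (7 and 3 adjusted over the list alone), with Ckap2 at 2.81 (SE 0.112), Cdkn1a at 2.39 (SE 0.108), Tigar at -1.15 (SE 0.120) and Sesn1 at -0.35 (SE 0.075). Their median was -0.03, their mean 0.40, and the test was upward at adjusted p = 0.029 (adjusted p = 0.48 with an estimated correlation). The p53 call ended with ranks (adjusted p = 0.19) and without WT replicate 3 (adjusted p = 0.076). Cdkn1a is also a member of the pocket protein list. Retinal progenitor genes rose in 13 of 16 cases and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.84 and a list test at adjusted p = 8.3e-09 (adjusted p = 0.22 with an estimated correlation). Hmgb2 stood at 2.68 (SE 0.127), Foxn4 at 2.26 (SE 0.158) and Gadd45a at -0.61 (SE 0.098). Polycomb and DNA methylation genes rose in 8 of 18 cases and 3 fell (10 and 4 adjusted over the list alone). The list had a median of 0.24 and an adjusted p of 0.0012 (adjusted p = 0.32 with an estimated correlation). Hells stood at 3.37 (SE 0.126), Uhrf1 at 2.63 (SE 0.114), Dnmt3a at -0.54 (SE 0.080) and Tet3 at -0.60 (SE 0.102). Hells and Uhrf1 are also members of the DNA replication list.

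Rod genes fell in 36 of 37 cases in DKO and none rose (36 adjusted over the list alone), with a median of -1.49 and a list test at adjusted p = 1.1e-16 (adjusted p = 0.34 with an estimated correlation). Nrl stood at -1.53 and Susd3 at -1.68 (SE 0.159). All 11 cone genes fell (11 adjusted over the list alone). At a median of -1.30 the list test gave adjusted p = 5.9e-07 (adjusted p = 0.25 with an estimated correlation). Examples were Pde6h (-1.93, SE 0.141) and the short-wavelength opsin gene Opn1sw (-1.5, SE 0.148). Bipolar genes fell in 20 of 28 cases and 3 rose (21 and 4 adjusted over the list alone), with a median of -0.87 and a list test at adjusted p = 1.4e-04 (adjusted p = 0.48 with an estimated correlation). Sebox (-1.19, SE 0.104) and Nyx (-0.87, SE 0.089) fell and Nfib (1.81, SE 0.123) and Prdm8 (0.82, SE 0.079) rose. Synaptic vesicle and presynaptic genes fell in 23 of 30 cases and none rose (23 adjusted over the list alone). The median was -0.41 and the adjusted p of the list test 2.0e-07 (adjusted p = 0.39 with an estimated correlation). Syngr1 stood at -0.85 (SE 0.098) and Rims2 at -0.75 (SE 0.088).

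**Figure D3:**
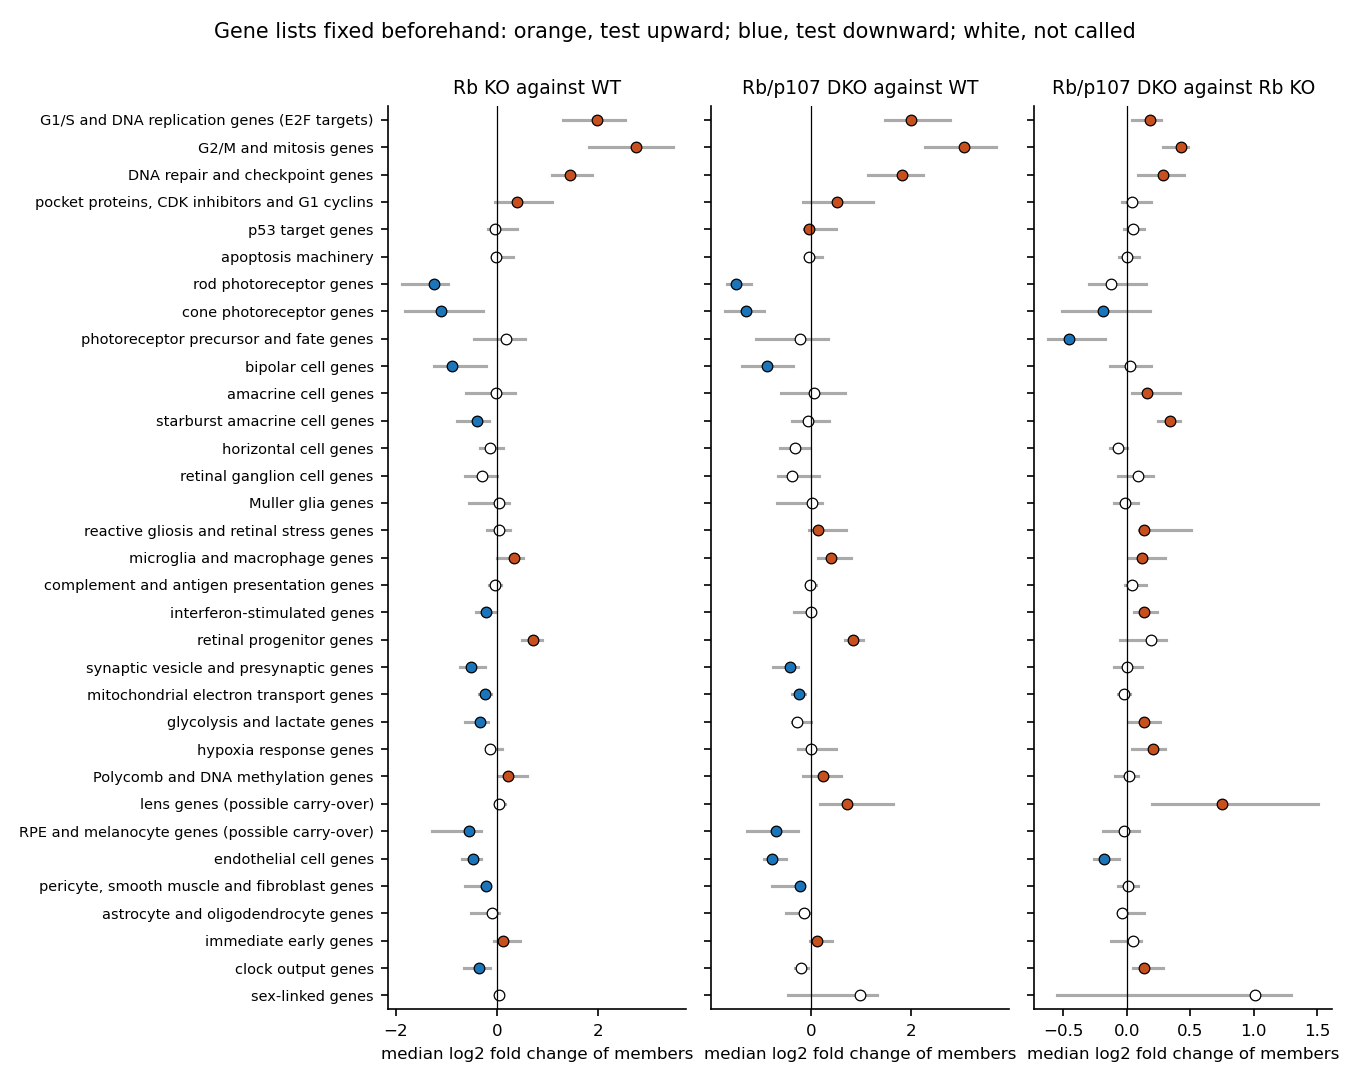
Median log2 fold change (horizontal axis, each panel on its own scale) of the measured members of each of 33 gene lists (vertical axis) in the 3 comparisons; circles are medians, grey lines run from the first to the last quartile boundary of the members, and filled circles are lists called at the fixed correlation of 0.01. Cell cycle lists lay furthest above 0 and rod and cone lists furthest below in both mutants, and no list was called with an estimated correlation.

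Microglia and macrophage genes rose in 15 of 30 cases in DKO and none fell (18 adjusted over the list alone), with a median of 0.41 and a list test at adjusted p = 6.7e-08 (adjusted p = 0.37 with an estimated correlation). Cd68 stood at 1.98 (SE 0.20) and the chemokine gene Ccl3 at 1.16 (SE 0.151). Gliosis and stress genes rose in 5 of 18 cases and 1 fell (5 and 1 adjusted over the list alone). Their median was 0.14, and the list test gave adjusted p = 0.0027 (adjusted p = 0.46 with an estimated correlation). Sox11 stood at 3.14 (SE 0.181), Mt1 at 1.37 (SE 0.111) and Osmr at -0.52 (SE 0.154), the last a call that ended without WT replicate 2 or 3 or DKO replicate 1 or 2 (adjusted p = 0.0607 to 0.109). Immediate early genes rose in 7 of 24 cases and 5 fell (8 and 5 adjusted over the list alone), with a median of 0.13 and a list test at adjusted p = 0.012 (adjusted p = 0.50 with an estimated correlation). Dusp1 (1.54, SE 0.119) and Ier2 (1.26, SE 0.138) rose and Nr4a1 (-0.56, SE 0.111) and Dusp5 (-0.51, SE 0.102) fell. The immediate early call ended without WT replicate 3 (adjusted p = 0.052).

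Endothelial genes fell in 16 of 19 cases in DKO and none rose (16 adjusted over the list alone), with a median of -0.77 and a list test at adjusted p = 4.0e-07 (adjusted p = 0.34 with an estimated correlation), with the lipid transporter gene Mfsd2a at -1.0 (SE 0.120) and Cldn5 at -1.06 (SE 0.132). Pericyte, smooth muscle and fibroblast genes fell in 8 of 15 cases (9 adjusted over the list alone). The list had a median of -0.21 and an adjusted p of 0.0029 (adjusted p = 0.34 with an estimated correlation). Vtn stood at -1.89 (SE 0.243) and Abcc9 at -1.07 (SE 0.152). Pigment epithelium and melanocyte genes fell in 14 of 18 cases and 1 rose (16 and 2 adjusted over the list alone), with a median of -0.70 and a list test at adjusted p = 1.4e-05 (adjusted p = 0.22 with an estimated correlation). Ttr stood at -2.19, Pmel at -1.58 (SE 0.135) and Ezr at 0.82 (SE 0.131). Mitochondrial electron transport genes fell in 21 of 47 cases and 1 rose (24 and 1 adjusted over the list alone). At a median of -0.23 the list test gave adjusted p = 1.5e-04 (adjusted p = 0.50 with an estimated correlation). Ppargc1b stood at -0.95 (SE 0.155), Ndufa4 at -0.55 (SE 0.093) and Nrf1 at 0.27 (SE 0.074), the last a call that ended without WT replicate 1 or 3 or DKO replicate 1 or 3 (adjusted p = 0.0544 to 0.102). The mitochondrial call ended with the control separation as a covariate (adjusted p = 0.14).

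Lens genes rose in 5 of 13 cases in DKO and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.73 and a list test at adjusted p = 0.0042 (adjusted p = 0.50 with an estimated correlation). Crybb1 (1.65, SE 0.360) and Cryaa (2.0, SE 0.498) rose and Cryab fell (-0.63, SE 0.201, adjusted p = 0.0374), the last a call that ended without WT replicate 1 or 2, Rb KO replicate 1, or DKO replicate 1 or 3 (adjusted p = 0.0591 to 0.125). The rise was uneven among the DKO arrays: relative to Rb KO, crystallins stood at 0.55, 2.12 and 0.49 and the other lens genes at 0.10, 0.74 and 0.02 in replicates 1, 2 and 3, the array highest in lens genes being the one with low Xist.

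Of the list members named in this comparison, Ccnd3, Nyx, Ccl3 and Osmr were not above the percentile of the negative controls in any WT or DKO array, so the sizes given for them are differences between background readings. Cdk2, Cdkn2c, Ckap2, Foxn4, Hells, Uhrf1, Cd68 and Ier2 were not above it in any WT array, nor Cdk6, Tigar, Susd3, Pde6h, Sebox, Cldn5, Mfsd2a, Abcc9, Pmel and Ppargc1b in any DKO array, and their sizes are not measured either. Genes of the lists not called in DKO against WT rose and fell as follows: 4 and 3 of 18 apoptosis genes, 3 and 4 of 11 photoreceptor precursor and fate genes, 11 and 8 of 25 amacrine, 2 and 3 of 10 starburst, 1 and 5 of 9 horizontal, 7 and 17 of 34 ganglion cell and 4 and 8 of 23 Muller glia genes. Complement and antigen presentation genes gave 1 and 1 of 15, interferon-stimulated genes 2 and 5 of 25, glycolysis and lactate genes 3 and 9 of 19, hypoxia genes 6 and 3 of 18, astrocyte and oligodendrocyte genes 1 and 5 of 14, and clock output genes 0 and 7 of 15. No gene passed among 5 sex-linked and 3 erythrocyte genes. Adjusted over the list alone the counts were 4 and 3 for apoptosis, 4 and 5 for precursor and fate, 11 and 9 for amacrine, 2 and 4 for starburst, 1 and 5 for horizontal, 7 and 19 for ganglion and 5 and 8 for Muller glia genes. They were 1 and 0 for complement, 2 and 5 for interferon-stimulated, 3 and 9 for glycolysis, 7 and 5 for hypoxia, 1 and 5 for astrocyte and 0 and 7 for clock genes. Signs of median, mean and test differed for apoptosis genes (-0.03, 0.16, upward), starburst genes (-0.06, -0.07, upward), Muller glia genes (0.02, -0.18, upward), complement genes (-0.01, 0.01, upward) and interferon-stimulated genes (0.01, -0.02, upward).

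Most changes from WT were common to both mutants. In both comparisons 4784 genes were called in the same direction, 2074 higher and 2710 lower, and 38 in opposite directions. The former were 80.8% of all calls in Rb KO. Independent lists of these sizes would share 301 higher and 592 lower genes. Both comparisons use the same 3 WT arrays, and unchanged groups simulated against shared controls had on average 0.01 genes called in both. The fold changes of the 2 comparisons correlated at 0.90 against 0.50 in the simulation, with covariances of 0.166 and 0.0062 and a difference of 0.160. The simulation shares the 3 controls, so it already takes up the random spread of the WT arrays, which gave 0.0062 of the covariance. A shift common to all 3 WT arrays would not appear in it. Such a shift may add to the excess, since 3 controls cannot be divided between the comparisons. Calls in Rb KO alone numbered 1101 and in DKO alone 2291.

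Fewer genes differed between DKO and Rb KO retinas than between either and WT. Neurog1, a proneural factor gene, rose by 1.5 in DKO against Rb KO (SE 0.143, 3 arrays per group, adjusted p = 2.7e-04), and Fezf1, a gene of ON starburst cells, by 1.76 (SE 0.350, adjusted p = 0.0279). Prdm1, which favours photoreceptor over bipolar fate, fell by 0.88 (SE 0.090, adjusted p = 4.7e-04) and Otx2, which starts photoreceptor fate, by 0.57 (SE 0.082, adjusted p = 0.00469). In all 324 genes rose and 293 fell, 53 and 63 of them at least 2-fold, a balance that turned toward falls in several alternatives (80 rose and 132 fell at an adjusted p under 0.01). Of 612 of these calls with a position, 356 were left without uncharacterised and multi-copy symbols. All counts of this paragraph take gene copies as separate genes. Of the 324, 79 were called higher and 146 lower in Rb KO than in WT, and of the 293, 85 were called higher and 85 lower. The Rb KO arrays enter both comparisons with opposite sign, so their noise alone favours opposite directions. The fold changes of these comparisons correlated at -0.00, against -0.50 in simulated unchanged groups, with covariances of -3.26e-04 and -0.0062. The simulated correlation follows from the shared arrays alone. It is no measure for data in which Rb KO differs from WT, so no conclusion is drawn from it.

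The other large rises in DKO against Rb KO were Mybpc1 (1.69, SE 0.097, adjusted p = 2.8e-05), Mmp12 (1.54, SE 0.280), and Steap4 (1.5, SE 0.340, adjusted p = 0.0465). The large falls were Gje1 (-2.21, SE 0.253), Erdr1 (-1.83, SE 0.326), St14 (-1.70, SE 0.116), Insm2 (-1.62, SE 0.138) and Arhgap31 (-1.55, SE 0.081, adjusted p = 1.6e-05). St14 and Insm2 were called higher than WT in Rb KO and did not lie above the percentile of the negative controls in any WT or DKO array. Arhgap31 was called higher than WT in Rb KO (0.84) and lower in DKO (-0.71). Mybpc1, Mmp12, Ccl3, Chek2, Clec7a, Fanci and Neurod6 were not above the percentile of the negative controls in any array of either mutant, so the sizes given for them are differences between background readings. Neurog1, Fezf1, Gje1, St14, Insm2, Otop3 and Ifit2 were not above it in any array of the lower group, with differences of at least 0.56, 0.21, 0.09, 0.64, 1.08, 0.56 and 0.40. Nor were Bhlhe40, Cenpa, Slc16a3, Ly86, Gfap, Hmox1 and Steap4, and their sizes are not measured either. For Fezf1 and Gje1 the bound was smaller than the SE of the fitted difference, so it sets no firm minimum.

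**Figure D4:**
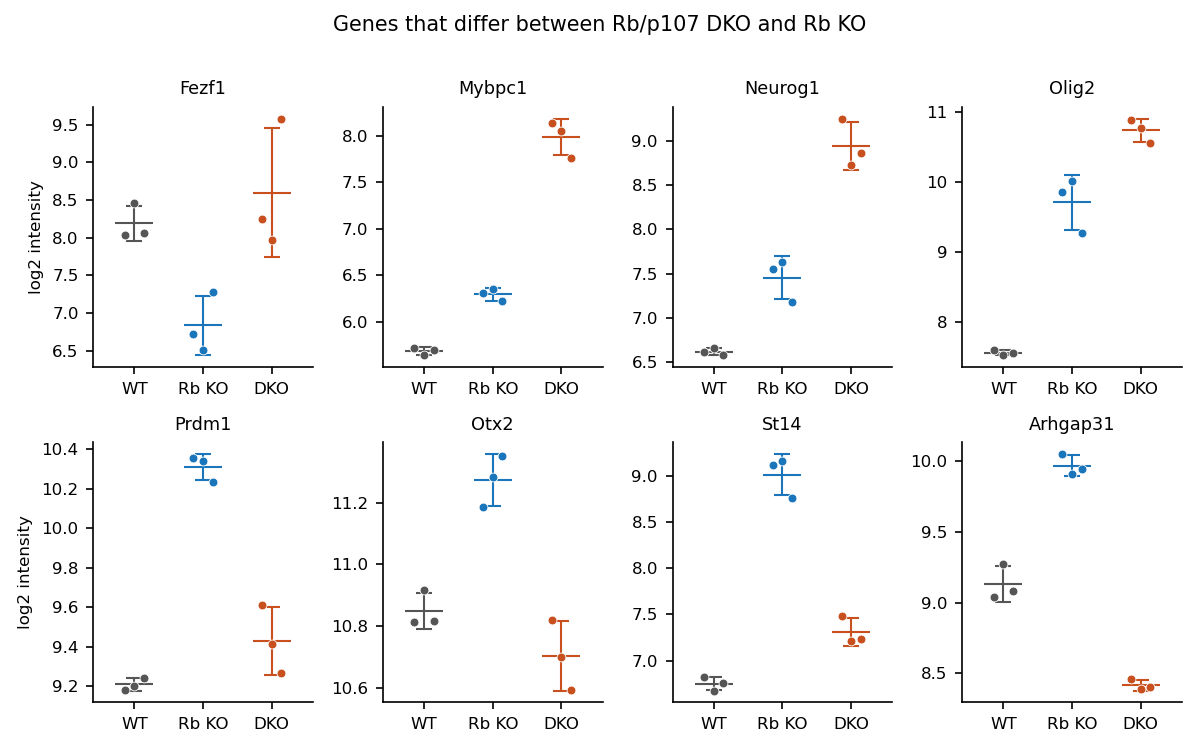
Log2 intensity (vertical axis) of 8 genes that differed between DKO and Rb KO in each array of WT, Rb KO and DKO (horizontal axis); points are arrays, horizontal lines group means and bars standard deviations over 3 arrays. Neurog1 and Olig2 were highest in DKO, whereas Prdm1, Otx2, St14 and Arhgap31 were highest in Rb KO.

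Photoreceptor precursor and fate genes were the list with the clearest fall between the mutants: 5 of 11 fell and 1 rose (6 and 1 adjusted over the list alone). The median was -0.45 and the adjusted p of the list test 5.0e-06 (adjusted p = 0.076 with an estimated correlation). Prdm1 and Otx2 rose in Rb KO against WT by 1.10 (SE 0.090) and 0.42 (SE 0.082) but did not pass in DKO against WT (0.22, adjusted p = 0.0933, and -0.15, adjusted p = 0.217). Olig2, a gene of neurogenic progenitors, rose by 1.02 between the mutants (SE 0.163). Cone genes fell in 3 of 11 cases and none rose (3 and 1 adjusted over the list alone), with a median of -0.19 and a list test at adjusted p = 0.015 (adjusted p = 0.62 with an estimated correlation). Otop3 stood at -1.22 (SE 0.125) and Gnb3 at -0.84 (SE 0.153). The cone call ended without Rb KO replicate 3 (adjusted p = 0.26) and without DKO replicate 1 (adjusted p = 0.34).

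Amacrine genes rose in 3 of 25 cases in DKO against Rb KO and none fell (6 adjusted over the list alone). Their median was 0.16, and the list test gave adjusted p = 8.8e-05 (adjusted p = 0.46 with an estimated correlation). Neurod6 stood at 0.76 (SE 0.152, adjusted p = 0.0294) and Barhl2 at 0.50 (SE 0.113, adjusted p = 0.0473). Of 10 starburst genes Fezf1 alone rose and none fell (8 adjusted over the list alone), with a median of 0.34 and a list test at adjusted p = 5.5e-06 (adjusted p = 0.23 with an estimated correlation).

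Cell cycle lists were called upward in DKO against Rb KO, though few of their members passed. Rotation tests called neither the G2/M (adjusted p = 0.14), the G1/S (adjusted p = 0.42) nor the repair list (adjusted p = 0.16). G2/M and mitosis genes rose in 5 of 36 cases (24 adjusted over the list alone). The list had a median of 0.43 and an adjusted p of 2.4e-17 (adjusted p = 0.46 with an estimated correlation). Cdc25c stood at 0.73 (SE 0.131) and Cenpa at 0.60 (SE 0.114). G1/S and DNA replication genes rose in 1 of 41 cases, Tk1 at 0.66 (SE 0.133) (5 adjusted over the list alone), with a median of 0.18 and a list test at adjusted p = 6.6e-06 (adjusted p = 0.69 with an estimated correlation), a call that ended without Rb KO replicate 3 (adjusted p = 0.066). DNA repair and checkpoint genes rose in 3 of 26 cases (11 adjusted over the list alone), with a median of 0.29 and a list test at adjusted p = 1.2e-08 (adjusted p = 0.52 with an estimated correlation). Fanci stood at 0.87 (SE 0.117) and Chek2 at 0.74 (SE 0.138).

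Gliosis and stress genes rose in 4 of 18 cases in DKO against Rb KO and none fell (6 adjusted over the list alone). At a median of 0.14 the list test gave adjusted p = 2.0e-05 (adjusted p = 0.46 with an estimated correlation). Gfap, the intermediate filament of reactive glia, stood at 0.78 (SE 0.161, adjusted p = 0.0297) and Hmox1 at 0.52 (SE 0.106, adjusted p = 0.0294). Gfap was called lower in Rb KO than in WT (-0.50, adjusted p = 0.0436) and did not pass in DKO against WT (0.28, adjusted p = 0.225). Microglia genes rose in 2 of 30 cases, Clec7a (1.42, SE 0.253) and Ccl3 (0.82, SE 0.151), and Ly86 fell (-1.26, SE 0.265) (4 and 1 adjusted over the list alone), with a median of 0.12 and a list test at adjusted p = 0.0041 (adjusted p = 0.78 with an estimated correlation). The microglia call ended without Rb KO replicate 3 (adjusted p = 0.64) and without DKO replicate 3 (adjusted p = 0.080). Of 25 interferon-stimulated genes Ifit2 rose (1.02, SE 0.128) and none fell (2 adjusted over the list alone). The median was 0.14 and the adjusted p of the list test 2.5e-05 (adjusted p = 0.52 with an estimated correlation).

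Metabolic and vessel lists differed slightly between the mutants. Glycolysis and lactate genes rose in 2 of 19 cases, Slc2a3 (0.67, SE 0.122) and Slc16a3 (0.56, SE 0.104) (4 adjusted over the list alone), with a median of 0.14 and a list test at adjusted p = 3.7e-04 (adjusted p = 0.53 with an estimated correlation). Of 18 hypoxia genes Bnip3 rose (0.68, SE 0.115) and Ndrg1 fell (-0.49, SE 0.078) (5 and 1 adjusted over the list alone), with a median of 0.21 and a list test at adjusted p = 8.4e-04 (adjusted p = 0.62 with an estimated correlation). Clock output genes rose in 2 of 15 cases, Bhlhe40 (0.90, SE 0.154) and Dbp (0.51, SE 0.105) (4 adjusted over the list alone), with a median of 0.14 and a list test at adjusted p = 4.3e-04 (adjusted p = 0.46 with an estimated correlation). No endothelial gene of 19 passed (3 lower adjusted over the list alone), but the list was called downward with a median of -0.18 at adjusted p = 3.7e-04 (adjusted p = 0.57 with an estimated correlation). Mfsd2a stood at -0.49 (SE 0.120, adjusted p = 0.0651) and Cdh5 at -0.57 (SE 0.152, adjusted p = 0.086). No lens gene of 13 passed (7 higher adjusted over the list alone), but the list was called upward with a median of 0.75 at adjusted p = 1.1e-04 (adjusted p = 0.57 with an estimated correlation). Crybb1 stood at 1.51 (SE 0.360, adjusted p = 0.0576) and Cryba1 at 2.01 (SE 0.586, adjusted p = 0.119).

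Many of these calls between the mutants lay near the threshold. Of the 34 called genes that the fixed rule named here, leaving out 1 array ended the calls of 21, with adjusted p between 0.0502 and 0.188. Without Rb KO replicate 1 or 3 or DKO replicate 1 or 3, the calls of Cdc25c, Cenpa, Chek2, Gnb3 and Bnip3 ended (adjusted p = 0.0504 to 0.0961). Without any Rb KO replicate or DKO replicate 1, those of Ccl3 and Mmp12 ended (0.0516 to 0.0824), without any Rb KO replicate or DKO replicate 1 or 3 those of Gfap and Slc16a3 (0.0538 to 0.117), and without any Rb KO replicate or DKO replicate 2 or 3 those of Hmox1 and Dbp (0.0572 to 0.126). Neurod6 lost its call without Rb KO replicate 1 or 3 or any DKO replicate (0.0592 to 0.0826), Tk1 without Rb KO replicate 2 or 3 or any DKO replicate (0.0598 to 0.12) and Barhl2 without WT replicate 3 or any Rb KO or DKO replicate (0.0639 to 0.188). Slc2a3 lost its call without Rb KO replicate 1 or 2 or DKO replicate 1 or 3 (0.0516 to 0.0811), Clec7a without Rb KO replicate 1 or 3 or DKO replicate 1 (0.057 to 0.0702) and Ly86 without WT replicate 3, Rb KO replicate 1 or 2 or DKO replicate 1 or 2 (0.0579 to 0.13). Bhlhe40 lost its call without Rb KO replicate 1 or 3 (0.0502 and 0.0538), Fezf1 without Rb KO replicate 1 or 2 (0.112 and 0.0794), Erdr1 without Rb KO replicate 1 or DKO replicate 3 (0.0667 to 0.083) and Steap4 without any WT or Rb KO replicate (0.0516 to 0.161). Neurog1, St14, Insm2, Arhgap31, Otop3 and Prdm1 passed in every alternative, and so did Mybpc1 apart from the one with brighter genes, which did not hold it.

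**Figure D5:**
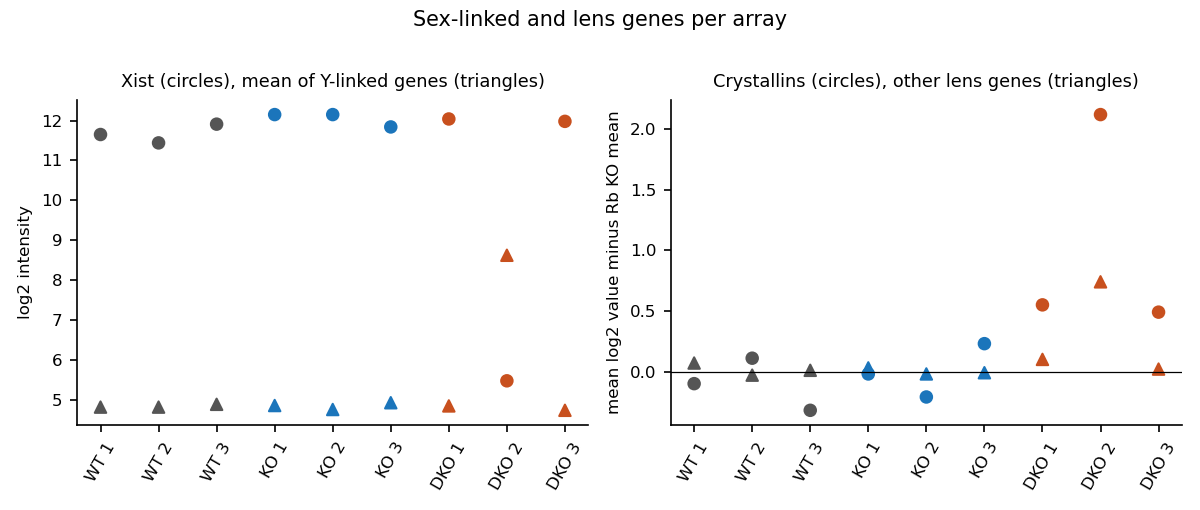
Per array (horizontal axis), log2 intensity of Xist (circles) and the mean of the Y-linked genes (triangles), and the mean log2 value of crystallins (circles) and other lens genes (triangles) minus their Rb KO mean. DKO replicate 2 had Xist at 5.47, Y-linked genes at 8.62 and crystallins at 2.12.

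In the lists not called between the mutants few genes passed. Genes rose and fell in 0 and 1 of 18 pocket protein and G1 cyclin, 1 and 0 of 21 p53 target, 0 and 2 of 37 rod, 0 and 2 of 9 horizontal cell, 1 and 3 of 34 ganglion cell and 0 and 1 of 23 Muller glia genes. The counts were 1 and 0 of 15 complement, 0 and 2 of 16 progenitor, 0 and 1 of 30 synaptic, 0 and 1 of 18 Polycomb, 1 and 0 of 14 astrocyte and oligodendrocyte and 0 and 3 of 24 immediate early genes. No gene passed among 18 apoptosis, 28 bipolar, 47 mitochondrial, 18 pigment epithelium, 15 pericyte, 5 sex-linked and 3 erythrocyte genes. Adjusted over the list alone the counts were 1 and 1 for pocket proteins, 1 and 0 for p53 targets, 0 and 3 for rod, 1 and 0 for bipolar, 0 and 2 for horizontal, 4 and 3 for ganglion and 0 and 1 for Muller glia genes. They were 1 and 0 for complement, 2 and 3 for progenitor, 1 and 1 for synaptic, 0 and 2 for Polycomb, 1 and 0 for pigment epithelium, 1 and 0 for astrocyte and 1 and 3 for immediate early genes. Signs of median, mean and test differed for Polycomb genes (0.02, -0.03, downward), pigment epithelium genes (-0.02, 0.06, downward), pericyte genes (0.01, 0.00, downward), astrocyte genes (-0.04, 0.06, upward) and immediate early genes (0.05, -0.01, downward).

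Genes of chromosome 14, which carries Rb1, were over-represented among the differences between DKO and Rb KO (odds ratio 2.58, adjusted p = 6.0e-10). The excess lay in uncharacterised multi-copy symbols: without them the odds ratio was 0.946 (adjusted p = 0.92), an alternative chosen after the data were seen. Chromosome 14 showed no such excess in Rb KO against WT (odds ratio 1.15, adjusted p = 0.12) or DKO against WT (odds ratio 1, adjusted p = 1).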

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

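The counts of probe sets without a gene symbol in this part were made after the array annotation was seen. The comparisons of the report used probe sets with 1 gene symbol, and 26476 transcript clusters had no listed symbol. These also held differences between the groups, a signal in data outside the comparisons above. Tested in the same limma model with all transcript clusters, 2776 of them (10.5%) differed in Rb KO against WT, 4165 (15.7%) in DKO against WT and 196 (0.74%) in DKO against Rb KO, against 18.7%, 23.9% and 1.44% of the transcript clusters with 1 symbol in the same fit. Of the differing clusters with no symbol, 1317, 2227 and 105 were higher. No explanation was tested, technical or biological, and no group of these probe sets was singled out.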

How the results depend on the processing

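The control separation covariate, the removal of uncharacterised and multi-copy symbols and the removal of WT replicate 2 together with DKO replicate 2 were alternatives chosen after seeing the data, and the rest were planned. The counts of genes changed in Rb KO against WT (5923) and DKO against WT (7113) stayed within 1.5 times their size in the other alternatives, and fell to 3309 and 4325 at an adjusted p under 0.01 and to 2079 and 2521 with a minimum of 1.5-fold, since fewer genes pass a stricter threshold. The number of genes that differed among the 3 groups, 6962, fell to 4198 at an adjusted p under 0.01, and calls shared by both mutants from 4784 to 2677, for the same reason. With single arrays left out, the counts ran from 4043 (without Rb KO replicate 2) to 6779 (without WT replicate 2) in Rb KO against WT and from 4911 (without DKO replicate 1) to 7867 (without WT replicate 2) in DKO against WT.

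The count between DKO and Rb KO, 617, depended on more choices. It was 1351 with array weights and 124 without variance shrinkage, and the cause was not tested. It was 212 at an adjusted p under 0.01 and 336 with a minimum of 1.5-fold, again because the thresholds are stricter. Leaving out single arrays gave 253 to 859: 253 without DKO replicate 3, 271 without DKO replicate 1, 302 without Rb KO replicate 1, 300 without Rb KO replicate 3 and 859 without WT replicate 2. With the sex covariate the counts of the 3 comparisons were 5209, 5887 and 513, with the control separation as a covariate 4321, 4974 and 636, without WT replicate 2 and DKO replicate 2 together 6257, 6659 and 665, and among the 14192 genes left without uncharacterised and multi-copy symbols 4868, 5730 and 498. Renewed scaling moved the median fold change of all genes by at most 0.049.

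The excess of falls over rises against WT depended on scaling. In Rb KO, 2465 genes rose and 3458 fell, against 3033 and 3238 with renewed quantile normalization and 2090 and 2231 with the control separation as a covariate. In DKO, 2960 rose and 4153 fell, against 3428 and 3984 and against 2474 and 2500. Between the mutants 324 rose and 293 fell. That balance turned at an adjusted p under 0.01 (80 and 132), without variance shrinkage (23 and 101), with renewed quantile normalization (336 and 375), without Rb KO replicate 1 (116 and 186) or 3 (118 and 182), without DKO replicate 1 (117 and 154) or 3 (100 and 153), without WT replicate 1 (271 and 272) and without uncharacterised and multi-copy symbols (241 and 257). The cause was not tested.

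Against WT, Rb1 changed sign in 1 alternative, which rests on readings at background. In Rb KO against WT its log2 fold change was -0.31 among genes brighter than the median gene, now past the threshold (adjusted p = 0.0428) as fewer genes were tested, and 0.68 with the mean of its probe sets (adjusted p = 0.00963), because the mean takes in a pair of probe sets not above the 95th percentile of the negative controls in any of the 9 arrays. Without single arrays it ran from -0.19 to -0.42, past the threshold without WT replicate 1 (adjusted p = 0.0302). In DKO against WT it turned to 0.74 with the mean of the probe sets (adjusted p = 0.00468). It stayed at -0.36 but lost its call with only 6 arrays (adjusted p = 0.0759), with all probe sets (0.0719), without variance shrinkage (0.109) and under both stricter thresholds. It lost the call at -0.31 with renewed quantile normalization (0.0848) and at -0.35 with median centring (0.0667). Without single arrays it ran from -0.23 to -0.46, and the call ended without WT replicate 2 (0.0569) or 3 (0.131), any Rb KO replicate (0.0575, 0.0521 and 0.0559), and DKO replicate 1 (0.153) or 3 (0.106). Between DKO and Rb KO it ran from -0.11 to 0.07 over all alternatives, never passing, and was above 0 with the mean of the probe sets and without Rb KO replicate 2 or DKO replicate 1. Apart from the mean of the probe sets, the cause of these changes was not tested.

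Gene list calls rested on the correlation assumed between genes. At the fixed 0.01 there were 20, 19 and 15 calls in Rb KO against WT, DKO against WT and DKO against Rb KO. With the correlation estimated by camera there were 0, 0 and 0, although 8670, 9581 and 3293 genes had an unadjusted p under 0.05, while the rotation test of limma (fry) called 23, 24 and 2 and ranks 21, 19 and 14. In DKO against Rb KO the calls left by fry were the photoreceptor fate list (adjusted p = 0.0035) and the starburst list (0.042). Among genes brighter than the median gene the interferon list (0.73) and the immediate early list (0.092) lost their calls in Rb KO against WT, the lens (0.12), p53 (0.40) and immediate early (0.18) lists in DKO against WT, and the microglia list (0.28) in DKO against Rb KO. Fry ended the microglia call in Rb KO against WT (0.061) and the lens call in DKO against WT (0.14), and ranks the cone call between the mutants (0.22). Fry also added calls. In Rb KO against WT it called p53 (0.0027), apoptosis (0.044) and photoreceptor fate genes (0.0019) upward and astrocyte genes (0.0077) downward. In DKO against WT it called apoptosis genes upward (0.021). Horizontal (0.0025), photoreceptor fate (0.037), glycolysis (0.033), astrocyte (0.012) and clock genes (0.0038) were called downward there. With the control separation as a covariate the starburst (0.091), interferon (0.089) and mitochondrial (0.069) calls ended in Rb KO against WT. The cause was not tested.

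Of the genes named by rule, 54 of 68 in Rb KO against WT, 56 of 70 in DKO against WT and 9 of 39 in DKO against Rb KO, Rbl2 included and Rb1 left out as given above, stayed on the same side of the threshold in every alternative that held them. Genes dimmer than the median gene were absent from the alternative with brighter genes and were judged by the others. The chromosome 14 odds ratio between the mutants fell from 2.58 to 0.946 (adjusted p = 0.92) without uncharacterised and multi-copy symbols, which were most of its calls. The F test with only 6 arrays has no 3 groups to compare and was not run.

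Replicate numbers did not pair the arrays: after removing group means, arrays of the same number correlated at -0.16 to 0.14, above 0.1 in 2 of 9 pairs, and 2 of 9 arrays correlated best with their own number. With a replicate block the counts were 5453, 6666 and 501, the F test gave 6322, 4465 calls were shared and 20, 19 and 15 lists were called. Rb1 then had -0.31 (adjusted p = 0.0622), -0.36 (adjusted p = 0.0326) and -0.05.

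All splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes were called in each comparison (4520, 6502 and 737 in fits to 6 arrays, 0 in the highest other split each time). Of 100 splits of the 9 arrays into 3 groups, drawn from 280, only the real one, 1 of 100, gave as many as 6962 genes. The highest other split gave 5138, and it kept the 3 WT arrays together while mixing Rb KO with DKO arrays. The count thus rests largely on WT against the mutants and says little of the split between Rb KO and DKO.

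Signal over background limits what can be seen of dim genes: between 27.2% and 36.4% of the genes lay above the 95th percentile of the negative controls.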

Other observations

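The bootstrap, covariate, neighbour and lens tests of this part were chosen after the data had been seen, and so were the genes of this paragraph and the next. As single genes outside the gene lists, H1f5 rose by 3.11 in Rb KO against WT (SE 0.165, higher in 3 of 3 arrays) and 3.36 in DKO, H3c3 by 3.34 (SE 0.178) and 2.93, and H2ac15 by 2.86 (SE 0.201) and 2.45. None of the 3 passed between DKO and Rb KO (adjusted p = 0.63, 0.34 and 0.431). No WT reading of these 3 genes lay above the 95th percentile of the negative controls, nor did any DKO reading of H3c3, so their sizes are not measured. Against that percentile the rises in Rb KO were at least 1.52, 0.28 and 1.78. Pou3f2, a neural transcription factor gene, was not above that percentile in any WT array and rose by at least 0.80 in DKO, and by 0.98 between the mutants (adjusted p = 0.00738).

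Of the 38 genes called in opposite directions in the mutants, 16 had characterised symbols, and 12 of these were higher than WT in Rb KO and lower in DKO. Among them were Ptpn21 (0.39 in Rb KO, -0.74 in DKO), Plcd1 (0.45 and -0.43) and Furin (0.26 and -0.27), though Plcd1 and Furin were not above that percentile in any DKO array. All 38 were also called between the mutants, where the opposite differences from WT add up, so this is no separate support. The other 22 were uncharacterised, small nucleolar RNA or olfactory receptor symbols, most of them on chromosome 14. In DKO against Rb KO a run of 4 neighbouring genes with the microRNA genes Mir182, Mir96 and Mir183 was lower on chromosome 6 (median -0.84), 23 neighbouring predicted genes were lower on chromosome 7 (median -1.17), and 18 neighbouring genes, mostly 5S ribosomal RNA copies, were higher on chromosome 8 (median 0.61). By chromosome, calls between the mutants were in excess on chromosome 8 (odds ratio 2.01, adjusted p = 1.2e-05) and scarce on chromosome X (0.467, adjusted p = 5.8e-04) and chromosome 4 (0.586, adjusted p = 0.023). Without uncharacterised and multi-copy symbols, left out after the data were seen, none of the 3 passed (odds ratios 1.06, 0.682 and 0.878, adjusted p = 0.82, 0.39 and 0.82). Chromosomes 8 and X also passed in Rb KO against WT (1.44 and 0.804, adjusted p = 4.9e-08 and 0.0018) and DKO against WT (1.25 and 0.778, adjusted p = 0.0012 and 1.1e-04), and neither passed without those symbols (adjusted p = 0.37 and 0.33, and 0.75 and 1). In DKO against WT chromosome 6 (0.787, adjusted p = 2.9e-04) and chromosome 19 (1.3, adjusted p = 0.002) passed, and did so without those symbols as well (0.808, adjusted p = 0.0087, and 1.29, adjusted p = 0.013). Without those symbols chromosome 7 then passed in Rb KO against WT (0.779, adjusted p = 8.0e-04) and chromosomes 7 (0.803, adjusted p = 0.0029) and 10 (1.3, adjusted p = 0.0029) in DKO against WT.

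Rod, cone and bipolar genes were lower in both mutants. Had RNA of cycling cells diluted every resting cell type, or the scaling shifted, Muller glia genes would have fallen as far as rod genes. For dilution this holds only if cycling cells do not express Muller glia genes. The rod median differed from the median of 22 of the 23 Muller glia genes by -1.26 in Rb KO (95% bootstrap interval -1.58 to -0.84). In DKO the difference was -1.48 (-1.72 to -1.06), and 6 of 6 rod, cone and bipolar intervals lay below 0. Against amacrine genes the rod differences were -1.21 (-1.63 to -0.82) and -1.55 (-2.17 to -1.05). These values argue against a shift of scaling as the whole cause. Dilution stays open, since cycling cells that express Muller glia or amacrine genes would hide it, which was not tested. Poorer hybridization of the mutant arrays would have taken most of the fall away once the control separation of each array was a covariate. The rod median was still -1.21 in Rb KO and -1.42 in DKO (list-test adjusted p = 3.1e-14 and 2.2e-13 at the fixed correlation). Without the covariate the rod list calls were lost with an estimated correlation (adjusted p = 0.30 and 0.34). Loss of whole photoreceptor cells stays open. The rod median lay below that of 6 photoreceptor fate genes (differences of -1.65, interval -2.21 to -0.76, and -1.52, interval -2.03 to -0.39). These 6 genes moved both ways, however. Crx (-0.46 and -1.06) and Casz1 (-0.47 and -1.125) fell in Rb KO and DKO. Neurod4 (0.70 and 0.525) and Rorb (0.38 and 0.47) rose in both, and Otx2 and Prdm1 rose in Rb KO but did not pass in DKO. The fall of the rod gene Nrl lay outside the interval of the rod median in Rb KO (-0.90, against -1.55 to -1.09). In DKO it lay within the interval (-1.53, within -1.67 to -1.24). The intervals of this paragraph were drawn over genes and hold no spread between arrays. Relative to WT the rod list means were -1.48, -1.73 and -0.99 in Rb KO replicates 1, 2 and 3. A difference between the mutants in Nrl relative to the rod genes was therefore not shown. Loss and delayed or reduced expression may thus both contribute and cannot be told apart.

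Genes that differed between DKO and Rb KO lay next to one another on the chromosomes more often than by chance. If near-identical gene copies read by the same probes were the whole cause, leaving out uncharacterised and multi-copy symbols would have ended the excess. Of 356 placed calls left, 19 pairs in the same direction were neighbours, against 4.48 expected and 14 at most in 10000 permutations (p = 1e-04, the smallest they can give), and with all symbols 115 pairs against 7.78. Segments of strain-specific sequence, possible on the mixed background, might add such pairs. The ratio to chance was 4.24, against 2.5 for as many top genes of Rb KO against WT, but neighbours that share regulation would raise it too, so the explanations cannot be told apart here.

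The lens list was called upward in DKO against Rb KO, though none of its 13 genes passed. The list call was lost with an estimated correlation (adjusted p = 0.57) and with fry (adjusted p = 0.31). The rise was largest in DKO replicate 2. Lens tissue carried over into that retina is a candidate explanation: lens genes other than the 8 crystallins, 5 measured, also stood 0.74 above their Rb KO mean in that array, against at most 0.03 in single Rb KO arrays. The 5 genes were uneven. Against their Rb KO means, Mip read 9.19 (6.97), Bfsp2 7.28 (6.48) and Lctl 6.21 (5.56) in that array. Lim2 (6.42, against 6.33) and Gja3 (6.38, against 6.42) hardly moved. For DKO replicates 1 and 3, whose crystallins stood 0.55 and 0.49 above that mean, the same carry-over predicted rises of the other lens genes of 0.18 and 0.12, and 0.10 and 0.02 were seen, with a standard deviation of 0.04 among WT and Rb KO arrays. The prediction rests on the profile of 1 array, so carry-over and higher crystallin expression of the retina itself cannot be told apart in these 2 arrays. DKO replicate 2 also differed in sex-linked genes: its low Xist and high Y-linked readings are the pattern of a male, those of all other arrays that of females. With a sex covariate 513 genes differed between the mutants in place of 617. As this array alone carries the difference, the covariate does not separate sex from the other peculiarities of the array. The effect of sex on the calls therefore stays open.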
